A study of Mus musculus with 12 samples.

How the data were processed

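Total RNA was sequenced from mouse embryonic stem cells of the line CJ9 that had been directed to endoderm or to mesoderm for 5 days. Per the labels' protocols, RNA was taken up in Trizol and purified on RNeasy columns with DNase, ribosomal RNA was depleted, and libraries were made with a directional kit and sequenced on an Illumina HiSeq instrument. The 12 libraries form 4 groups of 3, wild type or arid4b∆ in each lineage, and groups and replicate numbers were taken from the sample titles. Nothing in the labels says whether the 3 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

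The deposited table holds whole-number read counts per gene, 1 column per library, with Entrez identifiers and symbols. Per the submitters' processing notes, STAR, DESeq2 and the mouse build mm10 were used for the deposited counts; versions and the role of each tool are not given in the sources used here. The program that counted reads, its use of strand and the annotation are likewise not given in the sources used here, so genes with near-identical copies and antisense or overlapping genes could share reads. In the deposited table, 63 of the 12636 genes with at least 50 counts in all had the same counts as another gene in all 12 libraries. Of 19680 genes listed, 347 lacked a symbol and 346 of these were named from the RefSeq table by their Entrez identifier. For 26 genes the column of wild type endoderm library 1 held a calendar date in place of a count. These 26 genes were left out of the main tests and were tested separately on the other 11 libraries. How the dates arose, and whether the other columns of these genes are in place, was not checked. In the other libraries these genes held 0.0664% of the counts.

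The count of Rn45s, the ribosomal RNA precursor, took 79.7% to 82.4% of each library and was left out of library sizes and tests. The remaining 1949299 to 6678893 counts per library set the precision. Within a library, Mir6236 and Lars2, which hold ribosomal RNA sequence, took 49.7% to 69.5% of those counts and were kept. A floor of 3 counts corresponds to 0.449 to 1.54 CPM (counts scaled to library size) in single libraries. Counting intervals are exact 95% binomial intervals of the ratio of counts, with library size taken into account, and a gene without counts in a group was set to 3 counts over that group to bound its fold. Reads carried no molecular identifiers, so floors and intervals cover counting error only.

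Counts were analysed in R 4.3.3 with edgeR 4.0.16. Library sizes were scaled by the trimmed mean of M values, genes were kept by filterByExpr with a minimum count of 10, and 11635 genes were tested. All 12 libraries entered one fit of 4 group means without covariates, and contrasts were tested by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment over all tested genes at 0.05. The comparisons were knockout against wild type in each lineage, the difference between these effects (the interaction), and endoderm against mesoderm in each genotype. The biological coefficient of variation was 9.71%. Standard errors are the absolute log2 fold change divided by the square root of the F statistic. No pair of replicate libraries held identical counts, and each library counted as 1 sample. Chi-square per degree of freedom lay between 2.23 and 18.4. It took in Mir6236 and Lars2, whose shares differed between libraries, so it cannot tell separate cultures from technical libraries.

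Gene lists, 34 in number, were written before the data were examined, and 29 had at least 5 tested members. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 between genes, and again with an estimated correlation, with Benjamini-Hochberg adjustment over the fixed lists of a comparison. A list of interferon-stimulated genes was drawn up after the data were seen, was tested in the same way, and is not independent evidence. Gene positions are whole-gene spans of the RefSeq annotation of GRCm38.p6, the assembly released as mm10; 19602 genes had one.

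The genes named in each comparison followed a rule fixed before the data were examined. They are Arid4b, a panel of lineage and pluripotency genes whatever their result, and the 8 largest rises and 8 largest falls (5 and 5 for the interaction and the lineage comparisons). These had to pass the test with a mean of at least 5 CPM and no overlap between the groups' libraries (overlap was not asked of the interaction), and predicted gene models were left out. Up to 4 members with the smallest adjusted p were taken from each list described, so an order given within a list is by adjusted p and not by fold. Genes named for chromosomes 8 and Y, the date-damaged counts and the interferon list were chosen after their values were seen.

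The edgeR test was run on simulated counts, with 200 genes changed in each comparison. They were drawn from each gene's mean over all 12 libraries, its dispersion and the library sizes. Each change was made in a single group, and all other genes had equal means in all groups. The shares recovered therefore do not take in the larger number of genes called in the genotype comparisons, or genes nearly without counts in some groups. In 11200 genes for endoderm, 42.2%, 74.2% and 93.8% of genes changed by 1.5, 2 and 4-fold were recovered, with 5.52% false calls. In 11248 genes for mesoderm the shares were 34.3%, 73.1% and 90.8%, with 5.07% false calls. For the interaction, with 11256 genes, they were 14.9%, 50.8% and 81.3% (7.84% false). The lineage comparison in wild type, on 11144 genes, gave 39.1%, 62.1% and 95.2% (4.55% false), and that in knockout, on 11174 genes, gave 21.9%, 72.3% and 96.7% (11.2% false). A simulated slope of 0.3 between the lineage differences was measured as 0.260, and as 0.286 on held-out libraries.

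Alternatives fixed before the data were examined were DESeq2 1.42.0 with its own size factors and test, DESeq2 size factors within edgeR, limma-voom, no filter on low counts, a mean of at least 5 CPM, only the 6 libraries compared, a test against a 1.5-fold change, the replicate number as a block, and the removal of each library in turn. Those for the lists were an estimated correlation and the fry rotation test. Alternatives chosen after seeing the data were keeping Rn45s, leaving out Mir6236 and Lars2 as well, leaving out genes of chromosomes 8 and Y, and a replicate block shared by all groups.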

Results

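Expression was measured in mouse embryonic stem cells of the line CJ9, wild type or labelled as lacking Arid4b, after 5 days of direction to endoderm or to mesoderm, with 3 libraries in each of the 4 groups. Arid4b encodes a subunit of the SIN3-HDAC chromatin complex, and the series asks what part it plays in lineage commitment. Total counts per library lay between 10351074 and 35660108. After removal of the ribosomal RNA precursor Rn45s, 1949299 to 6678893 counts remained. Across the tested genes, the first principal component held 38.4% of the variance and separated the genotypes, and the second held 22.3% and separated the lineages.

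Arid4b (chromosome 13, 14063609 to 14199603) was counted at similar levels in all groups. Its level was 41.1 ± 3.98 CPM in wild type endoderm and 46.3 ± 4.29 in the libraries labelled knockout (SD, n = 3), and 42.1 ± 4.78 against 44.7 ± 2.99 in mesoderm. The difference was not called in endoderm (log2 fold change 0.17 ± 0.11 SE, edgeR adjusted p = 0.364) or in mesoderm (0.10 ± 0.12, adjusted p = 0.599). Whole-gene counts therefore cannot check the deletion, since reads outside a deleted part can remain. "Knockout" below stands for libraries labelled knockout, and every direction rests on those labels.

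In cells directed to endoderm, the genes that mark the primitive streak and the endoderm were lower in the libraries labelled knockout than in wild type. Foxa2, a forkhead factor of definitive endoderm (chromosome 2, 148042877 to 148046969), went from 24.5 ± 5.31 CPM to 0.619 ± 0.39 (SD, n = 3), a 41.8-fold fall. Sox17, an endoderm transcription factor (chromosome 1, 4490928 to 4497426), fell 24.1-fold from 20.6 ± 6.86 CPM, and T (brachyury), the T-box factor of the primitive streak and mesoderm (chromosome 17, 8434423 to 8442496), fell 42.2-fold from 46.5 ± 10.4 CPM. Pou5f1, the pluripotency factor Oct4, stood at 243 ± 25.7 and 256 ± 13.7 CPM and was not called (adjusted p = 0.69). Interferon-induced genes such as Usp18, a deconjugase of the ubiquitin-like protein ISG15, and Oas1a, an antiviral oligoadenylate synthetase, were 45.6-fold and 43.5-fold higher.

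Of the 14 panel genes tested in endoderm, 12 fell, 1 rose and 1 was not called. Sox2, a factor shared by pluripotent and neural cells, rose (log2 fold change 0.92 ± 0.19 SE, adjusted p = 0.00173). The falls included Gata6 (−4.48 ± 0.31, adjusted p = 1.45e-09), Mixl1 (−4.35 ± 0.35, adjusted p = 9.93e-09), Pdgfra (−3.86 ± 0.30, adjusted p = 7.68e-09) and Cxcr4 (−3.84 ± 0.38, adjusted p = 2.05e-07). Gata6 is an endoderm factor, Mixl1 a homeobox gene of the streak, Pdgfra a receptor of early mesoderm and Cxcr4 a chemokine receptor of definitive endoderm. Eomes, a T-box factor upstream of endoderm and mesoderm, changed by −2.93 ± 0.14 (adjusted p = 6.28e-12), Gata4 by −1.34 ± 0.24 (adjusted p = 0.000597) and Nanog, a pluripotency factor that is also active in the streak, by −1.19 ± 0.13 (adjusted p = 1.19e-06). For each of these genes all 3 knockout libraries lay outside the wild type range. Kdr, a VEGF receptor of vascular and cardiac progenitors (chromosome 5, 75932827 to 75979072), held 45 counts over the wild type libraries and 1 over the knockout libraries, a ratio of 50.2 (95% counting interval 8.56 to 2027; adjusted p = 0.000248). Mesp1, a factor of nascent mesoderm, held 15 against 1 count (ratio 16.7, interval 2.57 to 705; adjusted p = 0.0398). Its call ended with limma-voom (adjusted p = 0.0605) and without any of the 6 libraries of the comparison, with adjusted p from 0.0528 without wild type library 1 to 0.135 without wild type library 3. Over all its alternatives adjusted p lay between 0.00246 (no filter) and 0.137 (test against 1.5-fold).

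**Figure D1:**
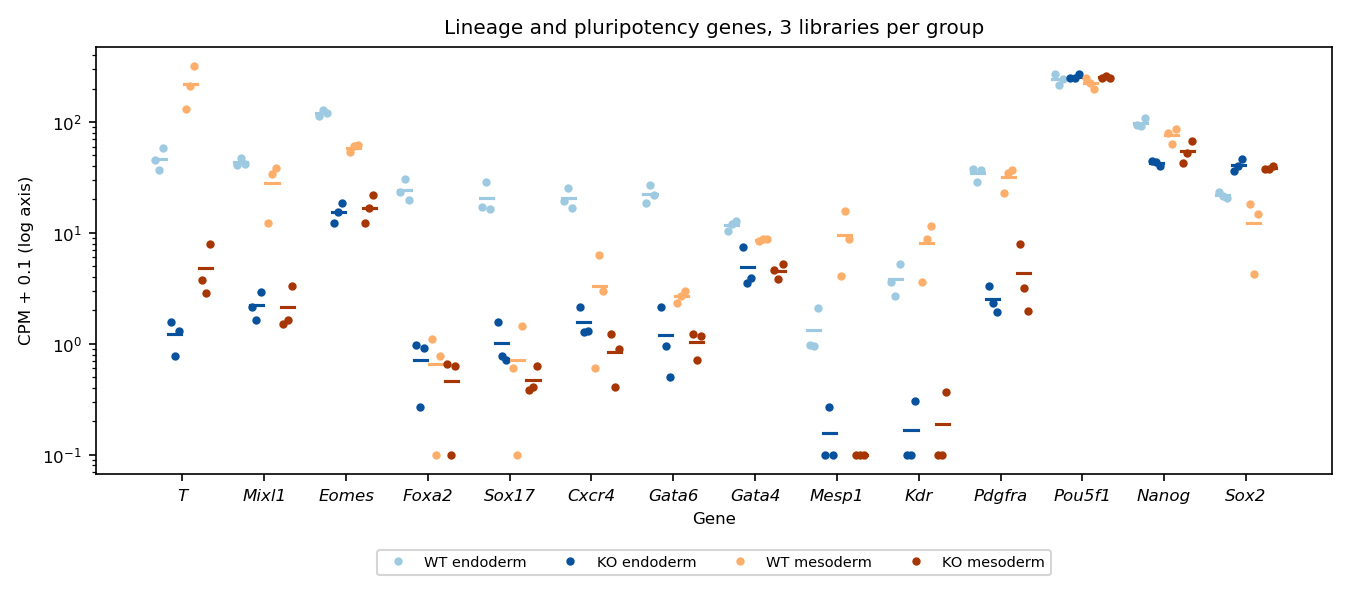
Levels of 14 panel genes in CPM plus 0.1 on a log axis, 1 point per library and a bar at the mean of the 3 libraries of a group. Mean levels of Foxa2 and Sox17 stand at 24.5 and 20.6 CPM in wild type endoderm and below 1.0 CPM in the other groups, while means of Pou5f1 lie between 224 and 256 CPM in all groups.

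Among the largest falls in endoderm were those of Cer1, Dkk1, Cfc1 and Lhx1. Cer1, a secreted inhibitor of Nodal, BMP and Wnt (chromosome 4, 82881751 to 82885151), held 971 counts in wild type and 3 in knockout, a ratio of 361 (95% counting interval 123 to 1754). Dkk1, a Wnt inhibitor, held 226 against 1 (ratio 252, interval 44.8 to 10004), and Cfc1, a Nodal co-receptor, 145 against 1 (ratio 162, interval 28.6 to 6434). Lhx1, a LIM homeobox factor of the anterior streak, fell from 59.1 ± 9.68 to 0.515 ± 0.295 CPM (log2 fold change −6.66 ± 0.31, adjusted p = 3.49e-12). The homeobox gene Gsc changed by −5.23 ± 0.43 (adjusted p = 1.36e-08) and Hs3st3b1, a heparan sulfate sulfotransferase, by −4.96 ± 0.57 (adjusted p = 2.13e-06). All 3 knockout libraries lay outside the wild type range for each of these, as the naming rule required.

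Lists of streak, endoderm, Nodal and Wnt genes were lower too. Of 16 tested primitive streak and mesendoderm genes, 14 fell and 1 rose (14 and 1 adjusted over the list alone; camera adjusted p = 2.9e-63, adjusted p = 0.000456 with an estimated correlation). The smallest adjusted p were those of Lhx1, Eomes, Cer1 and Sp5, a Wnt-responsive factor (log2 fold change −4.50). Of 17 definitive endoderm and early gut genes, 15 fell and 1 rose (15 and 1 adjusted over the list alone; adjusted p = 6.62e-35, adjusted p = 0.0035 with an estimated correlation). The gene that rose was Sox2. Of 18 Nodal target genes, 14 fell (15 fell and 1 rose adjusted over the list alone; adjusted p = 1.48e-47, adjusted p = 0.000456 with an estimated correlation). The streak, endoderm and Nodal lists share members, Cer1 among them. The Wnt list shares Sp5, T, Fgf8 and Wnt3 with the streak list, so results of these lists are not separate findings. Of 19 Wnt target genes, 10 fell (11 adjusted over the list alone; adjusted p = 8.02e-17, adjusted p = 0.00752 with an estimated correlation), with Sp5, Dkk1, T and the growth factor Fgf8 (−2.96) first. Of 6 haemato-endothelial genes, 3 fell, namely Flt1, a VEGF receptor (−3.76), Kdr and Runx1, a blood transcription factor (−1.80); the count was 3 adjusted over the list alone (adjusted p = 7.74e-06, adjusted p = 0.00752 with an estimated correlation).

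Members of other lists also fell in endoderm. Some of them stand in several lists, as Eomes in the streak, Nodal and trophoblast lists and Peg10 in the trophoblast and imprinted lists. Of 8 lateral plate and cardiac mesoderm genes, 5 fell (7 adjusted over the list alone; camera adjusted p = 9.35e-08, adjusted p = 0.014 with an estimated correlation), Gata6 and the ligand Bmp2 (−3.54) among them. Of 6 trophoblast genes, 3 fell (4 adjusted over the list alone; adjusted p = 5.52e-09, adjusted p = 0.0277 with an estimated correlation), namely Eomes, the AP-2 factor Tfap2c (−3.28) and the imprinted gene Peg10 (−1.78). Of 9 nascent and paraxial mesoderm genes, 4 fell (5 adjusted over the list alone; adjusted p = 0.000104), a call that ended at adjusted p = 0.121 with an estimated correlation. Of 17 extraembryonic endoderm genes, 6 fell, led by Gata6 and Sox17, and 1, the endocytic receptor Lrp2, rose (7 and 2 adjusted over the list alone; adjusted p = 0.00174, adjusted p = 0.429 with an estimated correlation, 0.0523 without knockout library 3). Of 14 FGF-ERK target genes, 4 fell, Il17rd, an inhibitor of FGF signalling (−1.37), first (5 fell and 1 rose adjusted over the list alone; adjusted p = 0.00633, adjusted p = 0.121 with an estimated correlation).

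Members of other groups rose in knockout endoderm. Besides Usp18 (log2 fold change 5.51 ± 0.45 SE) and Oas1a (5.44 ± 0.40), the largest rises were Gvin1, an interferon-inducible GTPase (4.96 ± 0.92, and 8.48 as fitted without wild type library 3), Oasl2 (4.65 ± 0.42), Mx2, an antiviral dynamin-like GTPase (4.60 ± 0.54) and Ddx58, the RNA sensor RIG-I (3.70 ± 0.25), with adjusted p of at most 0.00104. Ifit1, an interferon-induced RNA-binding protein, held 2 counts in wild type and 149 in knockout (ratio 66.8, 95% counting interval 18.2 to 556), and Rtp4 2 and 152 (ratio 68.1, interval 18.5 to 568). All 3 knockout libraries lay above the wild type range for each of these genes, as the naming rule required. Several of the genes have close paralogs that could share reads. In the list of 34 tested interferon-stimulated genes, drawn up after these genes were seen, 29 rose and 1, Ifitm1, fell (adjusted p = 4.64e-66, adjusted p = 4.13e-05 with an estimated correlation). Of 31 replication-dependent histone genes, 24 rose (31 adjusted over the list alone; adjusted p = 1.34e-12, adjusted p = 0.349 with an estimated correlation), as Hist1h1a at 0.59 ± 0.14. The Hist1h1a call ended without wild type library 2 (adjusted p = 0.0557; over its alternatives 1.22e-06 without a filter to 1.0 in the test against 1.5-fold). Of 23 G1-S and E2F target genes, 3 rose, the replication licensing genes Cdt1 and Gins2 among them (3 adjusted over the list alone; adjusted p = 0.0105, adjusted p = 0.42 with an estimated correlation).

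Some markers of fibroblasts, which serve as feeders for embryonic stem cells, rose in knockout endoderm as well, Col1a1, Postn and Fbln2 among them. Of 14 fibroblast and feeder genes, 4 rose and 10 were not called (11 rose adjusted over the list alone; adjusted p = 5.75e-06, adjusted p = 0.293 with an estimated correlation). Col1a1, a collagen chain, rose 4.30-fold to 45.4 CPM (log2 fold change 2.11 ± 0.45 SE, adjusted p = 0.00278), with 2 of 3 knockout libraries above the wild type range and knockout library 3 at 19.3 CPM against 20.4 in wild type library 1. Postn and Fbln2, matrix proteins, rose by 2.47 and 2.21, with all 3 knockout libraries above that range.

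Over all 11635 genes, 1478 were called in endoderm, 673 higher and 805 lower, and 594 of them differed by 2-fold or more. Groups of 3 libraries did not overlap for 30.2% of genes, against 10% by chance. The list test called 14 of the 29 lists tested, 11 lower and 3 higher, of which 8 were called with an estimated correlation. The count was 835 without wild type endoderm library 2, 914 with DESeq2 and 372 in the test against 1.5-fold.

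In cells directed to mesoderm, streak and mesoderm genes were lower in knockout. Pluripotency factors went different ways, with Sox2 and Utf1 higher, Nanog and Klf5 lower and Pou5f1 not called. T fell from 220 ± 93.1 to 4.73 ± 2.66 CPM (SD, n = 3), which is 45.7-fold. Mesp1 (chromosome 7, 79792241 to 79793590) held 98 counts in wild type and none in knockout, which puts it at least 29.0-fold lower with a floor of 3 counts over the group. Cdx2, a caudal homeobox factor of posterior mesoderm and trophoblast (chromosome 5, 147300900 to 147307249), held 196 counts against 1 (ratio 174, 95% counting interval 30.9 to 6919). Sox2 was 2.79-fold higher, from 12.3 ± 7.25 to 38.3 ± 1.4 CPM.

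Of the 14 panel genes in mesoderm, 9 fell, 1 rose and 4 were not called. T changed by −5.51 ± 0.32 (log2 ± SE, adjusted p = 4.77e-10), Mixl1 by −3.73 ± 0.40 (adjusted p = 9.11e-07), Pdgfra by −2.87 ± 0.30 (adjusted p = 5.43e-07) and Eomes by −1.79 ± 0.16 (adjusted p = 7.58e-08). Kdr held 99 counts in wild type and 1 in knockout (ratio 88.0, 95% counting interval 15.4 to 3512). For these genes and for Mesp1 and Sox2 all 3 knockout libraries lay outside the wild type range. Nanog changed by −0.53 ± 0.14 (adjusted p = 0.00843, 2 of 3 libraries), Gata4 by −0.95 ± 0.27 (adjusted p = 0.0171) and Gata6 by −1.43 ± 0.49 (adjusted p = 0.0457). Pou5f1 (0.18 ± 0.10, adjusted p = 0.249), Sox17 (adjusted p = 0.44), Foxa2 (adjusted p = 0.599) and Cxcr4 (adjusted p = 0.0654) were not called, and Sox17 and Foxa2 stood below 1.0 CPM in both genotypes. Hand1, a factor of lateral mesoderm, had 51 counts in all and was not tested. The Nanog call ended without wild type library 3 (adjusted p = 0.0638) and knockout library 1 (0.066), the Gata4 call without wild type library 3 (0.0658) and knockout library 2 (0.0711) and with DESeq2 (0.0777), and the Gata6 call with DESeq2 (0.115), with limma-voom (0.104) and without wild type library 2 (0.0668) or 3 (0.173) or knockout library 1 (0.0775), 2 (0.142) or 3 (0.0865). Over all alternatives adjusted p lay between 0.000163 and 1.0 for Nanog, 0.0104 and 0.376 for Gata4, and 0.0314 and 0.270 for Gata6, lowest without a filter and highest in the test against 1.5-fold.

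The largest falls in mesoderm also took in Sprr2a1 and Sprr2a2, paralogs of the cornified envelope on chromosome 3 whose counts were identical in every library, so that their reads cannot be told apart. Each held 1101 counts in wild type and 2 in knockout (ratio 490, 95% counting interval 135 to 4047). Aplnr, the apelin receptor of early mesoderm, held 166 against 3 (ratio 49.2, interval 16.5 to 241). Those 3 counts lay in knockout library 3, without which the log2 fold change of Aplnr went from −5.50 to −8.89. Sp5 changed by −4.94 ± 0.42 (log2 ± SE, adjusted p = 5.2e-08), Alox15, a lipoxygenase, by −4.88 ± 0.42 (adjusted p = 5.2e-08) and Cpxm2, a carboxypeptidase-like protein, by −4.10 ± 0.54 (adjusted p = 1.32e-05). The largest rises were led by Gvin1, with no count in wild type and 178 in knockout, at least 66.7-fold higher. Ifit3 (4.81 ± 0.66), Usp18 (3.93 ± 0.45), Oas1a (3.91 ± 0.37) and Ifit1 (3.68 ± 0.52), with adjusted p of at most 3.46e-05, are interferon-induced too. Kbtbd11, a kelch repeat protein encoded on chromosome 8, rose by 3.05 ± 0.28 (adjusted p = 1.31e-07), Lefty1, a secreted Nodal inhibitor, by 2.98 ± 0.33 (adjusted p = 1.32e-06) and Lgals3bp, a galectin-binding glycoprotein, by 2.96 ± 0.44 (adjusted p = 6.21e-05). All 3 knockout libraries lay outside the wild type range for each gene of these groups, as the naming rule required.

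Among the fixed lists, 11 of 16 streak and mesendoderm genes fell and 1 rose in mesoderm (11 and 1 adjusted over the list alone; camera adjusted p = 1.66e-24, adjusted p = 0.00714 with an estimated correlation). Of 19 Wnt target genes, 13 fell (15 adjusted over the list alone; adjusted p = 5.18e-19, adjusted p = 0.0128 with an estimated correlation), T, Sp5 and the ligand Wnt3 (−1.68) first. Of 9 nascent and paraxial mesoderm genes, 7 fell (9 adjusted over the list alone; adjusted p = 5.29e-13, adjusted p = 0.0216 with an estimated correlation), including Pdgfra, Cdx2 and Mesp1. Of 6 trophoblast genes, 5 fell (5 adjusted over the list alone, camera adjusted p = 4.38e-11, adjusted p = 0.0216 with an estimated correlation), Eomes, Peg10 (−3.01) and Cdx2 among them. Eomes is also in the streak list, Cdx2 in the Wnt and nascent mesoderm lists and Peg10 in the imprinted list. The Wnt and streak lists share T, Sp5 and Wnt3. Of 13 BMP target genes, 8 fell and 1 rose (8 and 1 adjusted over the list alone; adjusted p = 1.43e-05), with the homeobox gene Msx2 (−3.50) and the T-box gene Tbx3 (−2.83) among those that fell; the adjusted p = 0.0958 with an estimated correlation. Of 8 lateral plate and cardiac genes, 5 fell, among them Tbx20 (−2.16, and −3.25 without knockout library 3), a cardiac T-box factor (5 adjusted over the list alone; adjusted p = 0.0423, adjusted p = 0.271 with an estimated correlation, 0.0913 without wild type library 3).

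Core pluripotency genes rose in knockout mesoderm, 11 of 18, while 2 fell (11 and 2 adjusted over the list alone; adjusted p = 3.63e-07, adjusted p = 0.0958 with an estimated correlation). Examples are Utf1, a chromatin factor of embryonic stem cells (2.80 ± 0.19), Foxd3 (2.15 ± 0.29), Sox2 (1.48 ± 0.21) and L1td1, an RNA-binding protein (0.84 ± 0.11), as log2 ± SE. Of 18 formative and primed pluripotency genes, 12 rose and 4 fell (13 and 4 adjusted over the list alone; adjusted p = 9.6e-05, adjusted p = 0.148 with an estimated correlation), with Otx2 (1.95 ± 0.18) and Pou3f1 (2.00 ± 0.23), factors of the primed state, among those that rose. Naive pluripotency genes were not called as a list in mesoderm (adjusted p = 0.801) or in endoderm (adjusted p = 0.964). Of 31 histone genes, 30 rose (31 adjusted over the list alone; adjusted p = 1.55e-18, adjusted p = 0.235 with an estimated correlation), as Hist1h2ak (0.88 ± 0.13). Of 19 integrated stress response genes, 8 rose and 3 fell (10 and 4 adjusted over the list alone; adjusted p = 0.0137, adjusted p = 0.0958 with an estimated correlation), with Slc7a5, an amino acid transporter (1.09 ± 0.11), first. In the interferon list drawn up after the data were seen, 23 of 34 rose and 1 fell (adjusted p = 3.2e-22, adjusted p = 0.000837 with an estimated correlation). Of 14 fibroblast and feeder genes, 2 rose in mesoderm (4 adjusted over the list alone; adjusted p = 0.00564, adjusted p = 0.631 with an estimated correlation, 0.0900 without knockout library 1), and Col1a1 stood at 18.9 and 45.3 CPM (adjusted p = 0.0546).

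**Figure D2:**
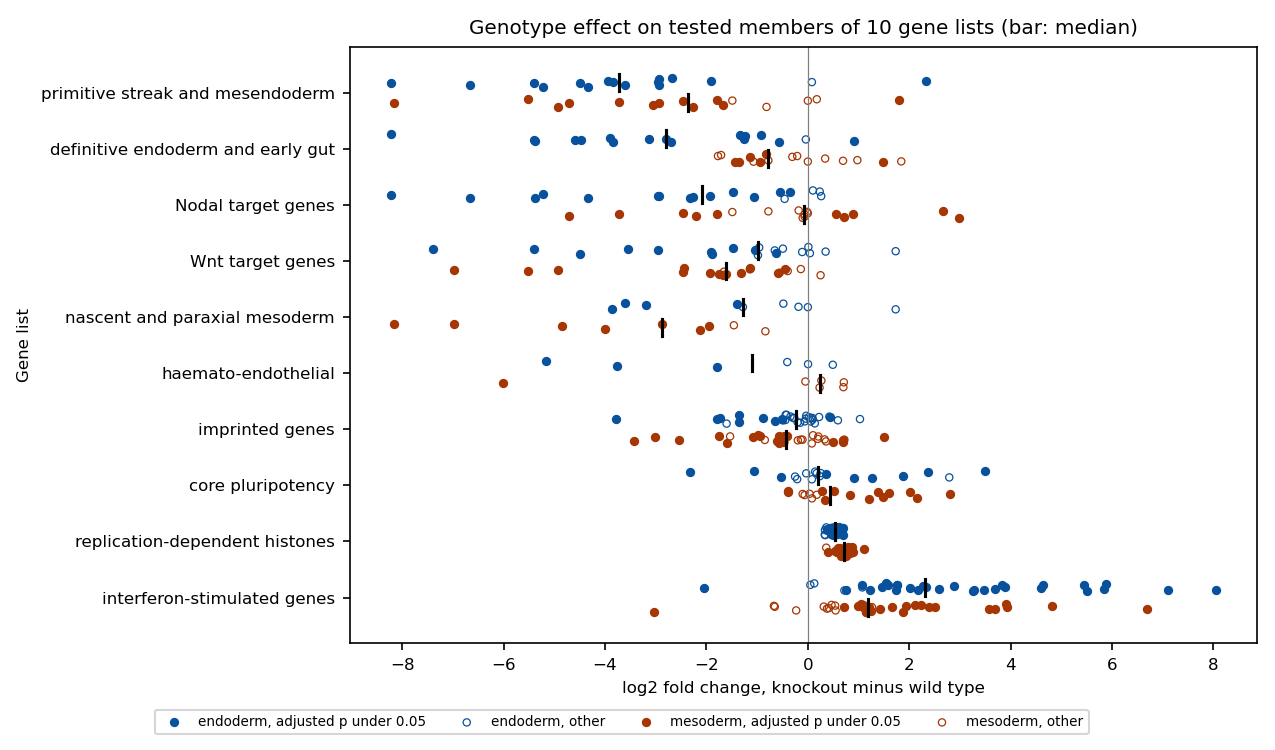
Log2 fold change, knockout minus wild type, of the tested members of 10 gene lists, 1 point per gene (filled where called) and a bar at the median, for endoderm and mesoderm. Of the streak genes, 14 of 16 fell in endoderm and 11 in mesoderm, while 29 and 23 of the 34 interferon-stimulated genes, a list drawn up after the data were seen, rose; points of genes without counts in a group are fitted values.

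In mesoderm 2224 genes were called, 1044 higher and 1180 lower, and 779 differed by 2-fold or more. Groups did not overlap for 32.8% of genes, against 10% by chance. The list test called 12 of 29 lists, of which 5 were called with an estimated correlation. The count was 1480 without wild type mesoderm library 3, 1448 with DESeq2 and 502 in the test against 1.5-fold. Wild type mesoderm library 1 lay nearer the knockout libraries on the first principal component, at −21.0 against −45.0 and −39.7 for libraries 2 and 3. Without it the count was 2461.

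The effects of genotype in endoderm and mesoderm were correlated across genes (Pearson r = 0.605, jackknife SE 0.0325 over libraries; Spearman rho = 0.565), though genes are not independent replicates. The comparisons share no libraries. Of the called genes, 411 were higher in both lineages where independent lists would give 60.4. Another 437 were lower in both where such lists would give 81.6, while 20 went opposite ways. Any lasting difference between the knockout and wild type cells would recur in both lineages, so the agreement does not tie an effect to Arid4b. Chromosome 8 alone held 120 of the 673 genes higher in endoderm and 162 of the 1044 higher in mesoderm. Neither r nor the overlap was computed without genes of chromosomes 8 and Y. The SE covers the choice of libraries and not that of method or of the genes correlated. The correlation was 0.351 with DESeq2, 0.280 without a filter and 0.667 among genes with a mean of at least 5 CPM. DESeq2 was run on unfiltered counts, so its value also takes in low-count genes and does not isolate an effect of method. With all libraries 848 genes moved in the same direction in both lineages, against 532 with DESeq2, 175 in the test against 1.5-fold and 524 without wild type endoderm library 2.

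The test of the difference between the lineages found a more negative effect of genotype in endoderm for Nodal target genes such as Lefty1 and Lefty2. These neighbouring genes for Nodal inhibitors (chromosome 1, 180935022 to 180938401 and 180893108 to 180899107) each fell in endoderm and rose in mesoderm. Lefty1 went from 78.2 ± 12.1 to 28.7 ± 4.93 CPM in endoderm and from 1.5 ± 0.493 to 10.9 ± 1.86 in mesoderm (SD, n = 3), a log2 difference of −4.46 ± 0.35 (SE, edgeR adjusted p = 2.3e-07). Lefty2 differed by −4.59 ± 0.52 (adjusted p = 2.06e-05) and the forkhead gene Foxq1 by −4.81 ± 0.86 (adjusted p = 0.00344). Foxq1 lay near the floor in mesoderm, at 1, 0 and 0.51 CPM in wild type and 1.12, 1.23 and 0.54 in knockout. A fall there could not be measured, so its difference rests on the fall in endoderm. Trh, which encodes thyrotropin-releasing hormone and was not called in mesoderm (adjusted p = 0.0653), differed by −3.77 ± 0.44 (adjusted p = 2.8e-05). Flt1 differed by −3.71 ± 0.37 (adjusted p = 3.57e-06). On the positive side, Nrp2, a semaphorin and VEGF co-receptor, fell in mesoderm from 44 ± 17.4 to 6.42 ± 2.94 CPM and stood at 1.65 ± 0.422 and 5.24 ± 4.44 in endoderm (difference 4.33 ± 0.73, adjusted p = 0.0016). Mx2 (3.35 ± 0.75, adjusted p = 0.0227), Oasl2 (2.77 ± 0.59, adjusted p = 0.014), the GABA receptor subunit Gabra3 (2.73 ± 0.48, adjusted p = 0.00294) and the interferon-induced GTPase Irgm1 (2.72 ± 0.32, adjusted p = 3.02e-05) followed. Without wild type mesoderm library 3, the difference was 1.46 for Mx2 (adjusted p = 0.644) and 1.73 for Oasl2 (adjusted p = 0.173), the highest adjusted p of their alternatives.

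Of the panel, Eomes (−1.15 ± 0.22, adjusted p = 0.00699) and Gata6 (−3.05 ± 0.71, adjusted p = 0.0311) differed between lineages. Gata6 stood at only 2.25, 2.58 and 2.87 CPM in wild type mesoderm, which limits the fall that could be measured there. Foxa2 (adjusted p = 0.0884), Sox17 (adjusted p = 0.222) and T (adjusted p = 0.996) did not pass, so a lineage difference of these was not shown. The Eomes call ended without knockout mesoderm library 3 (adjusted p = 0.0618). The Gata6 call ended without wild type endoderm library 2 (0.0653), knockout endoderm library 2 (0.079) or 3 (0.0647), or knockout mesoderm library 1 (0.157), 2 (0.055) or 3 (0.143). The Mx2 call ended with limma-voom (0.138) and without wild type endoderm library 1 (0.0742), 2 (0.107) or 3 (0.063), wild type mesoderm library 3 (0.644) or knockout mesoderm library 2 (0.055). The Oasl2 call ended with limma-voom (0.0677) and without wild type endoderm library 1 (0.0614) or 2 (0.122) or wild type mesoderm library 3 (0.173). Over all alternatives adjusted p reached 0.214 for Eomes, 0.157 for Gata6, 0.644 for Mx2 and 0.173 for Oasl2, and was lowest without a filter (1.49e-06, 0.00183, 5.54e-07 and 3.09e-07).

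As lists, 6 of 18 Nodal target genes had a more negative effect in endoderm (8 adjusted over the list alone; camera adjusted p = 2.76e-20, adjusted p = 0.00496 with an estimated correlation). In mesoderm alone 5 Nodal targets rose and 5 fell (5 and 5 adjusted over the list alone), and the list was not called (adjusted p = 0.206). For 17 definitive endoderm genes the number was 5 (8 adjusted over the list alone; adjusted p = 1.73e-12, adjusted p = 0.0401 with an estimated correlation). For 18 formative genes it was 5, with 1 in the other direction (10 and 1 adjusted over the list alone; adjusted p = 2.48e-10, adjusted p = 0.0401 with an estimated correlation), and Otx2 (−2.20 ± 0.23) and Fgf5 (−2.51 ± 0.33) led it. Of 6 haemato-endothelial genes, Flt1 and Runx1 differed (2 adjusted over the list alone; adjusted p = 2.78e-05, adjusted p = 0.0227 with an estimated correlation), and of 14 FGF-ERK targets 5 did, Egr1 (−2.09 ± 0.44) and Etv4 (−1.49 ± 0.32) among them (6 and, in the other direction, 2 adjusted over the list alone; adjusted p = 8.1e-05, adjusted p = 0.0416 with an estimated correlation). Over all genes 163 had an interaction, 73 positive and 90 negative. The count was 105 without wild type endoderm library 2, 104 without knockout mesoderm library 2 and 354 without wild type mesoderm library 1, 377 without a filter on low counts and 55 in the test against 1.5-fold.

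**Figure D3:**
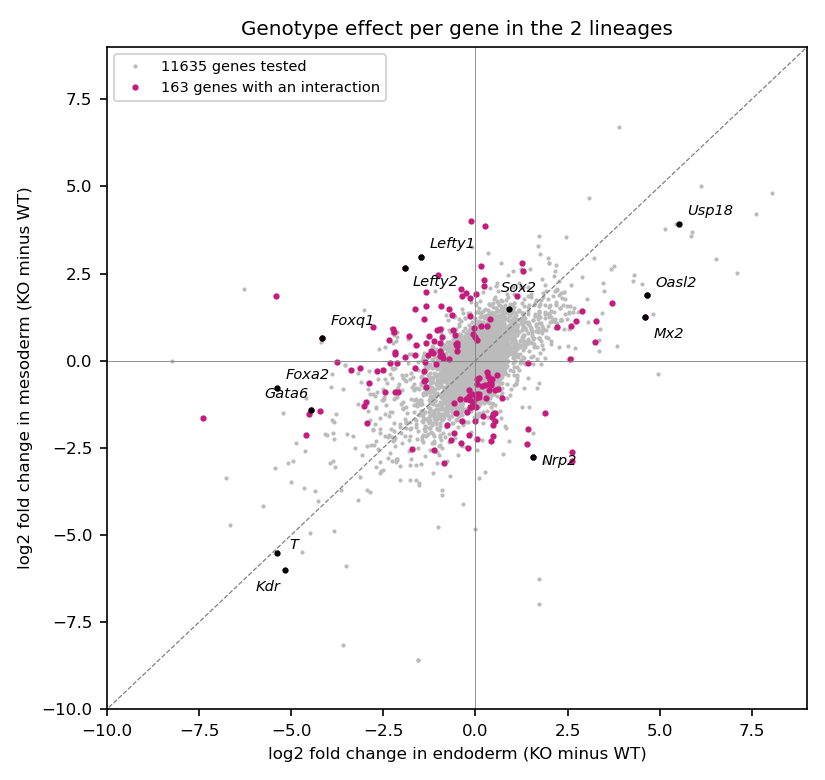
Log2 fold change, knockout minus wild type, of 11635 genes in endoderm (x axis) and mesoderm (y axis), with the 163 genes that had an interaction in colour, named genes in black and a dashed line of equal effects. Lefty1 lies below 0 in endoderm and at 2.98 in mesoderm, while T lies near the line at −5.40 and −5.51.

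In wild type cells Cer1, Foxa2 and Lefty1 were higher in endoderm cultures, and Cdx2 and T in mesoderm cultures. Cer1 held 971 counts in endoderm and none in mesoderm, at least 300.5-fold higher. Foxa2 was 35.4-fold higher in endoderm (log2 difference 5.14 ± 0.38 SE, adjusted p = 5.97e-09), Lefty1 56.8-fold (5.83 ± 0.24, adjusted p = 5.04e-13), Foxq1 37.3-fold (5.22 ± 0.38, adjusted p = 4.82e-09) and Gsc 31.9-fold (5.00 ± 0.44, adjusted p = 6.66e-08). Cdx2, without a count in endoderm, was at least 70.4-fold lower there, and T was lower by −2.27 ± 0.23 (adjusted p = 3.48e-07). Tfap2a, an AP-2 factor of surface ectoderm and neural crest, held 2 counts in endoderm and 178 in mesoderm (ratio 95.8, 95% counting interval 26.1 to 798). Sprr2a1 and Sprr2a2, which share reads, differed by −7.41 ± 0.73 (adjusted p = 2.9e-07) and Cpxm2 by −5.04 ± 0.59 (adjusted p = 3.11e-06). All 3 endoderm libraries lay outside the mesoderm range for each of these genes, which the naming rule required of all but T.

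Of the panel, Sox17 (4.62), Gata6 (3.11), Cxcr4 (2.94) and Eomes (1.04) were also higher in wild type endoderm and Mesp1 (−2.85) lower, while 7 of the 14 genes were not called. Of 17 definitive endoderm genes, 12 were higher (14 adjusted over the list alone; camera adjusted p = 1.35e-34, adjusted p = 0.00516 with an estimated correlation), and of 18 Nodal targets 10 (12 adjusted over the list alone; adjusted p = 1.13e-38, adjusted p = 0.000649 with an estimated correlation). Of 13 BMP targets, 10 were lower (11 adjusted over the list alone; adjusted p = 7.18e-22, adjusted p = 0.00516 with an estimated correlation), among them Id1 (−2.90 ± 0.22) and Id2 (−3.14 ± 0.27), inhibitors of bHLH factors. Of 13 naive pluripotency genes, 8 were lower (9 lower and 1 higher adjusted over the list alone; adjusted p = 2.94e-09, adjusted p = 0.0976 with an estimated correlation), Klf5 (−2.24) and Zfp42 (−3.27) among them. Of 9 nascent and paraxial mesoderm genes, 6 were lower (6 adjusted over the list alone; adjusted p = 4.08e-08, adjusted p = 0.061 with an estimated correlation). The lateral plate and cardiac mesoderm list was called higher in endoderm, with 3 of 8 genes higher and 2 lower (4 and 2 adjusted over the list alone; adjusted p = 0.0106, adjusted p = 0.146 with an estimated correlation). Gata6 and Bmp2 (2.38) were among the higher genes and Bmper, a BMP-binding protein (−2.82), among the lower ones. The call of this list ended without endoderm library 1 (adjusted p = 0.0549) or 2 (0.0736) or mesoderm library 1 (0.399). The streak list was called higher too, with 6 of 16 genes higher and 5 lower (7 and 6 adjusted over the list alone; adjusted p = 0.00107, adjusted p = 0.159 with an estimated correlation), a call that ended without mesoderm library 1 (adjusted p = 0.399). Of 18 formative genes, 9 were higher and 1 lower (13 and 2 adjusted over the list alone; adjusted p = 3.84e-09, adjusted p = 0.061 with an estimated correlation). Of 6 haemato-endothelial genes, 2 were higher and 1 lower (2 and 3 adjusted over the list alone); the median was −0.56, the mean 0.22 and the test direction higher (adjusted p = 0.0464, adjusted p = 0.146 with an estimated correlation). That call ended without any endoderm library (adjusted p = 0.251, 0.150 and 0.290) and without mesoderm library 1 (0.641) or 2 (0.0904). Of 14 fibroblast genes, 3 were lower in endoderm (4 adjusted over the list alone; adjusted p = 0.0118, adjusted p = 0.507 with an estimated correlation, 0.0818 without endoderm library 2 and 0.281 without mesoderm library 1). In all 1145 genes were called, 513 higher and 632 lower, 18 lists passed and 3 passed with an estimated correlation. The count was 753 without wild type endoderm library 2, 740 without wild type mesoderm library 3 and 404 in the test against 1.5-fold.

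In knockout cells Igfbp5 and Id1 were among the genes that differed between lineages. Igfbp5, an IGF-binding protein, was 10.2-fold higher in endoderm, at 115 ± 20.8 against 11.2 ± 5.08 CPM (SD, n = 3; log2 difference 3.35 ± 0.22, adjusted p = 6.22e-09), and Id1 7.57-fold lower (−2.92 ± 0.26, adjusted p = 9.29e-07). Slitrk5, a neuronal membrane protein (2.04 ± 0.30), Ddah1, an enzyme of dimethylarginine breakdown (1.52 ± 0.28), Pak3, a kinase (1.48 ± 0.31), and Atp10d, a lipid flippase (1.42 ± 0.13), were higher. Dnah8, a dynein heavy chain (−3.04 ± 0.59), Dnmt3l, a cofactor of DNA methylation (8.03-fold), Tdh, threonine dehydrogenase of naive cells (−2.81 ± 0.51), and Id2 (−2.44 ± 0.29) were lower. Adjusted p was at most 0.0113 for these, and all 3 endoderm libraries lay outside the mesoderm range, as the naming rule required. The calls of Pak3 and Dnah8 ended without knockout endoderm library 2 (adjusted p = 0.0681 for each) and knockout mesoderm library 3 (0.104 and 0.118), that of Dnah8 with limma-voom (0.0671), and that of Tdh without knockout mesoderm library 3 (0.0712). Over all alternatives adjusted p lay between 0.000279 and 0.212 for Pak3, 3.98e-29 and 0.118 for Dnah8, and 8.12e-13 and 0.0712 for Tdh.

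No panel gene passed the edgeR test between knockout lineages, while 2 of 14 had an unadjusted p under 0.05. T stood at 1.12 ± 0.398 and 4.73 ± 2.66 CPM (log2 difference −2.16 ± 0.75, adjusted p = 0.174) and passed with DESeq2 (adjusted p = 0.041), while limma-voom gave 0.422; over its alternatives adjusted p lay between 2.74e-06 without a filter and 1.0 in the test against 1.5-fold. Of 13 BMP targets, 5 were lower in endoderm (8 adjusted over the list alone; camera adjusted p = 4e-21, adjusted p = 0.0111 with an estimated correlation), and of 13 naive pluripotency genes 7 were (10 adjusted over the list alone; adjusted p = 7.39e-17, adjusted p = 0.069 with an estimated correlation). Knockout mesoderm library 3 stood apart on naive genes (Dppa5a at 80.5 CPM, against 27.2 and 28.4 in the other 2 libraries), and both list calls held without each library in turn. The definitive endoderm list was not called (adjusted p = 0.473). In all 215 genes were called, 110 higher and 105 lower, and 11 lists (17 without knockout endoderm library 1), 1 of them with an estimated correlation. The gene count was 83 without knockout endoderm library 2, 133 without knockout endoderm library 3, 120 without knockout mesoderm library 2, 59 without knockout mesoderm library 3, 127 with DESeq2, 483 without a filter and 26 in the test against 1.5-fold.

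Over the 1145 genes that separated the lineages in wild type, regressing the knockout difference on that in wild type gave a slope of 0.272 (jackknife SE 0.0794). Choosing genes on the difference regressed on lowers such a slope, and with genes chosen on 2 wild type libraries per lineage, the difference in the held-out wild type libraries had slopes of 0.494, 0.806 and 0.771. As a ratio to the held-out wild type difference, which would be 1 without a change, the knockout slope averaged 0.293, from 0.239 to 0.393. Of these genes 151 had an interaction, 132 were called in knockout in the same direction, and 5 in the opposite one.

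Position also marked the genotypes. The 647 tested genes of chromosome 8 had a median log2 fold change of 0.23 in endoderm and 0.27 in mesoderm, with 78.1% and 76.0% of them above 0, and 120 of the 140 called in endoderm and 162 of the 190 called in mesoderm were higher. The Y-linked genes Ddx3y, an RNA helicase, Eif2s3y, a translation initiation factor subunit, and Uty, a histone demethylase homologue, fell in endoderm (−3.80, −2.66 and −3.66) and mesoderm (−3.05, −2.53 and −3.71). Without genes of chromosomes 8 and Y, 1335 genes were called in endoderm and 2026 in mesoderm.

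**Figure D4:**
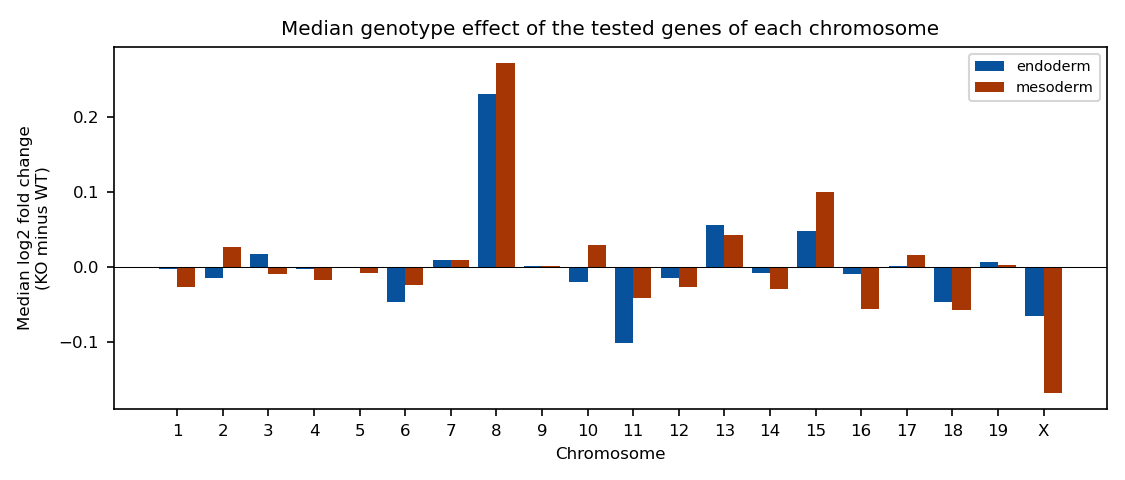
Median log2 fold change, knockout minus wild type, of the tested genes on each chromosome (bars from 0, x axis chromosome), for endoderm and mesoderm. Chromosome 8 stands at 0.23 and 0.27; chromosome Y, with medians of −2.21 and −2.87 over 8 genes, is left off the axis.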

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

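Tests chosen only after the result was seen are those of scaling for chromosome 8, of the loss of the Y chromosome, of wild type cells among knockout cells and of library size and fibroblast cells as the whole source for the interferon genes, as was the interferon list itself.

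The genotype effect differed between lineages (tested as an interaction) for Lefty1 (−4.46), Lefty2 (−4.59), Foxq1 (−4.81), Trh (−3.77), Flt1 (−3.71), Eomes (−1.15) and Gata6 (−3.05), with the effect in endoderm the more negative, and for Nrp2 (4.33), Mx2 (3.35), Oasl2 (2.77), Gabra3 (2.73) and Irgm1 (2.72) in the other direction. Foxq1 lay near the floor in both mesoderm groups and Gata6 was low there, which limits the falls that could be measured in mesoderm. Without wild type mesoderm library 3 the values were 1.46 for Mx2 (adjusted p = 0.644) and 1.73 for Oasl2 (adjusted p = 0.173). The Mx2 call also ended without any wild type endoderm library or knockout mesoderm library 2, and the Oasl2 call without wild type endoderm library 1 or 2. The Eomes call ended without knockout mesoderm library 3 (adjusted p = 0.0618), and the Gata6 call without wild type endoderm library 2, knockout endoderm library 2 or 3 or any knockout mesoderm library (at most 0.157).

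In all 163 genes had an interaction, 105 without wild type endoderm library 2, 104 without knockout mesoderm library 2 and 354 without wild type mesoderm library 1. Regrouping the libraries within lineages gave as many genes in 7 of 100 regroupings drawn, the real one included. Of the 6 others, 5 kept the genotype groups of 1 lineage whole, and 1, which called 3284 genes, kept those of both and swapped the genotypes in mesoderm. The structure behind these counts is the genotype effect itself, which such regroupings carry into the interaction by construction. The 75 that kept neither lineage whole called at most 0 genes by edgeR (710 at an unadjusted p under 0.05, against 1206 for the real grouping), but they mix genotypes within groups and so add that effect to the spread. Whether chance can be excluded for the 163 genes is therefore not answered by these regroupings.

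The fixed lists whose effect differed between lineages had median log2 differences of −2.07 for definitive endoderm (−2.01 without members that lack counts in a group), −1.06 for Nodal targets (−0.97 without such members), −0.74 for formative, −0.69 for haemato-endothelial and −0.25 for FGF-ERK target genes. Core pluripotency genes had −0.13, with 4 of 18 past the test in that direction (6 adjusted over the list alone), Tdgf1, a Nodal co-receptor (−2.25), first (adjusted p = 2.48e-06, adjusted p = 0.107 with an estimated correlation). Integrated stress response genes had −0.45 (1 of 19 genes past the test, Cth, in the other direction; 7 and 2 adjusted over the list alone; adjusted p = 0.0126, adjusted p = 0.0828 with an estimated correlation). Histone genes had −0.16 and cytosolic ribosomal protein genes −0.14, with 0 members called by edgeR (0 adjusted over the list alone; adjusted p = 0.0126 for each list, adjusted p = 0.923 with an estimated correlation). These 2 calls ended without wild type mesoderm library 3 (medians −0.01 and −0.02, adjusted p = 0.803 and 0.769), wild type endoderm library 1 (0.601 and 0.379) or knockout endoderm library 2 (0.192 and 0.540), the histone call also without knockout endoderm library 3 (0.272) or knockout mesoderm library 1 (0.215), and the ribosomal call without knockout mesoderm library 3 (0.0650).

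The 16 tested genes of the 26 with a calendar date for a count were Septin and Marchf genes, Mtarc2 and Selenof. Of these, 3 were lower in knockout mesoderm, namely Septin8 (−0.63), Septin9 (−0.36) and Septin6 (−0.53). These results hold only if the other columns of the damaged genes are in place, which was not checked.

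For each comparison of 3 libraries with 3, the splits are too few for a share under 0.05. The real split, 1 of 10, called 1478 genes in endoderm, 2224 in mesoderm, 1145 between wild type lineages and 215 between knockout lineages by edgeR, and the highest other split called 0 in each. Every other split mixes the groups compared and so adds their difference to the spread, so that these counts of 0 exclude nothing. At an unadjusted p under 0.05 the real and highest other counts were 2934 and 707, 3628 and 1011, 2514 and 967, and 1474 and 768.

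Genes of chromosome 8 were higher in knockout. In both lineages 13 of 13 windows along the chromosome had a median above 0.1, and the difference from other autosomes was 0.213 to 0.284 in knockout libraries and −0.0627 to 0.0456 in wild type libraries. Scaling is argued against, as the largest median of another autosome reached at most 44.3% (36.9% in the other lineage) of that of chromosome 8. Smaller shifts were not confined to chromosomes 8 and Y. Chromosome 11 had a median of −0.10 in endoderm, with 33.8% of genes above 0. The X chromosome, which this test left out, had medians of −0.06 in endoderm and −0.17 in mesoderm, with 41.7% and 34.5% above 0. Regulation of a minority of genes is argued against by a share of genes above 0 that exceeded the other autosomes' by 26.2 and 30.0 percentage points. Extra copies of chromosome 8 in part of the knockout cells may explain it, a hypothesis without a DNA measurement, and an effect of Arid4b on the whole chromosome was not tested.

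All 8 tested genes of chromosome Y had a log2 fold change below 0 in both lineages, with medians of −2.21 and −2.87. The same 8 genes had a median of −1.97 between endoderm and mesoderm in wild type, so these medians also hold genes that vary with lineage. The 3 with at least 5 CPM in wild type of both (Ddx3y, Eif2s3y and Uty) overlapped between the wild type lineages and stood at 7.07% to 16.7% of wild type in knockout. Loss of the Y chromosome from most cells and lower transcription of the chromosome cannot be told apart, because each predicts these falls in RNA and no DNA was measured. Wild type cells as the source of the remaining reads are argued against, if such cells express as the wild type cultures do. The 5 strongest falls kept 1.69% of wild type in endoderm and 1.95% in mesoderm, which is 16.5% and 16.4% of the 10.2% and 11.8% kept by the Y-linked genes.

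Interferon-stimulated genes summed to 190 ± 3.46 CPM in wild type and 736 ± 60.1 in knockout endoderm, and to 379 ± 64.6 and 748 ± 13.6 in mesoderm (SD, n = 3). Without the 3 members that lack counts in a group, the median log2 difference between the genotype effects was 0.98, endoderm minus mesoderm. Between the lineages in wild type it was −1.08. In each lineage every knockout library lay above every wild type library, 6 of 6 in all. That separation is no independent evidence, since the list was drawn up after its genes were seen higher in knockout. Library sizes overlapped between the genotypes, which argues against library size as its source. Fibroblast or feeder cells as the source of the whole rise of the summed list are argued against, if collagen transcripts follow their share. Summed collagen in the 4 knockout libraries below the highest of their lineage was 24.5% to 50.4% of that highest. In these libraries 81.6% to 102% of the interferon excess over wild type remained (smallest gap 35.8 percentage points). Knockout endoderm library 3 had 42.2 CPM of collagen, below the 54.3 of a wild type library, with an interferon sum of 691 CPM. The sum does not speak for each gene. From knockout library 1 to 3, Gvin1 fell as collagen did, at 18.36, 10.87 and 4.26 CPM in endoderm. In mesoderm it stood at 32.25, 12.04 and 6.42 CPM, and Ifit3 fell in the same order in both lineages. Oasl2 did not, at 18.07, 17.32 and 19.88 CPM in endoderm and 20.19, 20.68 and 24.08 in mesoderm. Wild type library 1 held Col1a1 at 20.43 CPM in endoderm and 30.02 in mesoderm, close to the 19.27 and 31.04 of knockout library 3. Gvin1 was at 0 CPM in both of these wild type libraries, and Ifit3 at 0 and 0.75. Knockout library 3 held Ifit3 at 4.46 and 8.56 CPM. Collagen alone thus did not set the level of these genes, though the comparison rests on few libraries. How many genes follow collagen was not tested. A smaller part from such cells cannot be told apart from a response of the cells themselves, as 1 of 3 collagen transcripts was less than 2-fold higher in a lineage (Col3a1, from 6.23 to 8.67 CPM in mesoderm) while Col1a1 and Col1a2 reached 45.3 and 33.2 CPM there, and an effect of Arid4b stays open.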

How the results depend on the processing

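The replicate block shared by all groups was chosen after seeing the data, as were the tests with Rn45s kept, with Mir6236 and Lars2 left out and of lists without members on chromosomes 8 and Y. Of 151 called results of named genes, 115 stayed called in every alternative run, and 0 of 199 reversed. Of the lists, 1 reversed, that of cytosolic ribosomal proteins between knockout lineages, not called with all libraries (median −0.01; −0.10 without knockout endoderm library 1, 0.0892 without library 2). DESeq2 called 914 genes in endoderm (881 shared), 1448 in mesoderm (1405 shared) and 127 between knockout lineages (121 shared), with 532 in the same direction in both lineages and r = 0.351. It was run on counts without the edgeR filter, so this r also takes in low-count genes that edgeR did not test. The test against a 1.5-fold change, by construction stricter, called 372, 502, 55 (interaction), 404 (wild type lineages) and 26 (knockout lineages) genes and 175 in both. Without a filter the interaction had 377 genes, the knockout lineages 483, and r was 0.280; with a mean of at least 5 CPM r was 0.667. Except where stated, the cause was not tested. With an estimated correlation 8, 5, 5, 3 and 1 lists passed (endoderm, mesoderm, interaction, wild type and knockout lineages), by directional fry 11, 12, 7, 14 and 7, and by mixed fry 28, 27, 14, 25 and 15. Leaving out each library in turn gave 835 to 1320 genes in endoderm, 1480 to 2461 in mesoderm, 104 to 354 for the interaction, 740 to 1391 and 59 to 237 between lineages in wild type and knockout, r of 0.555 to 0.591, 524 to 953 genes in both a slope of 0.212 to 0.307, and 8 to 17 lists between knockout lineages. Alternatives for normalized values were not run, since the values are counts. With 1949299 to 6678893 counts per library, genes near the floor of 0.449 to 1.54 CPM are limited by counting.

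A replicate block nested in lineage gave 1853 genes in endoderm, 2532 in mesoderm, 346 for the interaction, 1396 and 443 between lineages in wild type and knockout. With the nested replicate block Gata6 was not called in mesoderm (adjusted p = 0.0540; 0.0314 to 0.270 over its alternatives). The replicate block shared by all groups gave 255 for the interaction and 377 between knockout lineages. Libraries with the same number had correlated deviations of 0.0132 to 0.193 in 12 pairs, 5 of them over 0.1. In 8 pairs both libraries correlated best with their own number. This held for every pair of endoderm and mesoderm within a genotype. Between knockout and wild type of a lineage it held only for libraries numbered 1. The block nested in lineage pairs knockout with wild type, and a block nested in genotype was not run. These correlations are a hint of pairing from the data and not from the design, since the labels give only a number.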

Other observations

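Subunits of chromatin complexes changed in a few cases. Of 23 tested SIN3-HDAC complex genes, 1 rose and 2 fell in endoderm and 1 rose and 3 fell in mesoderm (1 and 2, then 4 and 4, adjusted over the list alone; camera adjusted p = 0.964 and 0.712). Rbbp7, a histone-binding subunit encoded on the X chromosome, fell by 0.96 ± 0.12 in endoderm and by 1.25 ± 0.12 in mesoderm (log2 ± SE). Tet1, a 5-methylcytosine oxidase that binds SIN3A, rose by 0.61 and 0.63, and Bbx, a HMG-box protein, fell in mesoderm by 1.13 ± 0.13. Of 25 polycomb genes, 2 rose and 2 fell in endoderm and 4 rose and 3 fell in mesoderm (the same counts adjusted over the list alone; adjusted p = 0.906 and 0.776). Among them Phc2 fell by 1.14 and 1.24 and Bmi1 by 1.20 and 0.89, both subunits of repressive complex PRC1, while Phc1 rose by 0.51 and 0.38.

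Among imprinted genes, more fell than rose in knockout. Of 32 tested, 8 fell and 1 rose in endoderm (10 and 2 adjusted over the list alone; camera adjusted p = 3.17e-05, adjusted p = 0.0095 with an estimated correlation), and 14 fell and 4 rose in mesoderm (16 and 5 adjusted over the list alone; adjusted p = 0.000326, adjusted p = 0.0315 with an estimated correlation). Peg3, a zinc finger gene expressed from the paternal allele, fell by 1.73 in endoderm and by 2.54 in mesoderm. Mest, a hydrolase gene, fell by 1.36 in endoderm and rose by 0.50 in mesoderm, and Phlda2, a growth regulator of the placenta, fell by 3.44 in mesoderm. Counts do not separate the alleles. The lists tested here were fixed before the data were examined, and the genes named from them were chosen with the results in view.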
